A study of Mus musculus with 5 samples.

How the data were processed

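Gene expression was measured in the colon of mouse embryos at stage E18.5, with 1 array for each of 5 embryos. The HNF4 null group held 3 embryos (null_59, null_60 and null_426) that carried 2 floxed HNF4 alleles and a FoxA3Cre transgene. The control group held 2 embryos (CONTROL_406 and CONTROL_421) that carried 1 floxed allele with the same transgene and were therefore heterozygous. Total RNA was isolated with Qiagen RNeasy mini columns, labelled with biotin and processed by the array maker's (Affymetrix) usual procedure, per the labels' protocols.

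The deposited table gave 1 intensity per probe set and array on a linear scale. The software that summarised probes into probe sets, the scaling between arrays and the background step were not given in the sources used here. Some values lay below 0, so some subtraction had been made before deposit. Scanner files were not used here. The table held 22690 probe sets, of which 64 control probe sets of the array maker were left out, and 22626 were tested. A platform annotation of 2016 paired 20380 of the tested probe sets with 1 gene symbol and 691 with several, and 1555 were unnamed here. By gene ID, 20351 of the probe sets with 1 symbol matched a table of mouse RefSeq genes (assembly GRCm38.p6), which changed 0 symbols. No gene was named from a probe set with several symbols.

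Values below 0 were set to 0 and all values were taken as log2(intensity + 16). The medians of the 5 arrays spread over 0.11 on this scale, more than the 0.1 set as the limit for using the table as deposited, so the arrays were quantile normalised to each other. No filter on dim probe sets was applied. A fold change is on the log2(intensity + 16) scale and understates the change of genes of low intensity. Intensities given with an SD are the deposited values. The number of arrays limits the precision. The p-values of single probe sets measure spread between these 5 embryos, with a variance prior drawn from all probe sets. Those of gene lists with a preset correlation rest largely on spread between genes.

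HNF4 null was compared with control for each probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate). The p-values were adjusted by Benjamini and Hochberg's method over all 22626 probe sets, and an adjusted p under 0.05 was the threshold. The total degrees of freedom, from the 3 residual ones and the prior, were 9.33. Intervals are 95% confidence intervals from the same fit.

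A gene with several probe sets was represented by the one with the highest mean over all 5 arrays, which gave 12393 genes. On these genes, 26 lists were tested with limma's camera (two-sided, preset correlation between genes of 0.01), adjusted over the 26 lists. The lists covered endoderm transcription factors, goblet cells, enterocytes and the brush border, lipids and apolipoproteins, colonic ion and water transport, xenobiotic metabolism, enteroendocrine cells, Wnt targets and progenitors, and proliferation. They further covered epithelial junctions and keratins, hedgehog and related signalling, smooth muscle, fibroblasts and matrix, enteric neurons and glia, endothelium, erythroid cells, macrophages and leukocytes, interferon response, and immediate early and stress genes. The last ones covered pancreas, liver, stomach, stratified squamous epithelium, small intestine over colon, mesothelium and reference genes. Camera was repeated with the correlation estimated from the data, and fry was run beside it. Counts of list members are given over all probe sets tested and adjusted over the list alone.

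Genes were named by a rule. It took Hnf4a, and then up to 12 genes with the largest decrease and up to 12 with the largest increase among those past the threshold by their representative probe set, if all 3 null arrays lay on 1 side of both control arrays. It also took from each list the 4 members with the smallest unadjusted p. The groups, the test, the threshold, the lists, this rule and the alternative settings were fixed before the data were examined. Genes outside the rule are said to be so where they appear in the report, and those in the closing section were chosen from all probe sets after their values were seen.

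The alternatives were the table as deposited, median centring, pseudocounts of 1 and 64, removal of dim probe sets, an intensity trend in the variance prior with and without the robust option, array weights, the mean of a gene's probe sets, the estimated correlation in camera and each array left out in turn. With 1 control array left, that array was assumed to vary like the null arrays.

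The scripts were tested on simulated data of 22626 probe sets with the group sizes of this comparison, of which 200 were changed. In 20 simulations, 45.6% of the 2-fold, 97.7% of the 4-fold and 99.8% of the 8-fold changes passed the threshold, and 5.49% of the calls were false. Every simulated list of 26 genes shifted by -0.5 on the log2 scale had an unadjusted camera p under 0.05 (100%), as did 0% of unshifted lists. The simulated genes varied independently of each other, so these lists do not test the preset correlation.

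In the closing section, 4 further lists (posterior Hox genes, urothelium, resident macrophages and lymphatic vessels) were written after the comparison had been seen. The question of another segment of the hindgut was first to be decided by the median of the posterior Hox genes alone, and a rule on its single members (beyond 0.5 at an unadjusted p under 0.05) was added after their values were seen. For the macrophage and lymphatic lists, a requirement was added likewise that most members lie above the median intensity of the control arrays and that these meet the same bound. The median of a list is given there with a 95% interval from 10000 bootstrap resamples of its members.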

Results

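Transcript levels in the fetal colon were compared between 3 HNF4 null and 2 control embryos at stage E18.5, by 1 array each. HNF4 proteins are nuclear receptors of the gut epithelium, liver and kidney, and the floxed gene is named only as HNF4 in the labels. The Cre transgene is named for Foxa3, a transcription factor gene of the gut endoderm. The comparison asks which colonic transcripts differ when both HNF4 alleles rather than 1 carry loxP sites. Median deposited intensities were 129.9, 131.7 and 135.2 for HNF4 null_59, null_60 and null_426, and 131.6 and 123.7 for CONTROL_406 and CONTROL_421. Across probe sets, log2 values of pairs of arrays had Pearson correlations from 0.946 to 0.974, and the probe sets are not independent replicates. The 2 control arrays correlated at 0.958, and CONTROL_406 correlated with HNF4 null_60 at 0.973. The ratio of the 3' to the 5' control probe set of Gapdh was 1.47 in CONTROL_421 and between 0.767 and 0.895 in the other arrays. The other control ratios did not set this array apart in the same way, since that of the transferrin receptor was lowest in it (1.51 against 2.69 to 3.48) and that of actin was 1.76, against 1.83 in HNF4 null_60 and 1.44 to 1.55 in the rest.

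Hnf4a, which encodes HNF4 alpha, was measured by 4 probe sets, and none of them passed limma's threshold. At an unadjusted p under 0.05, 1 of the 4 differed. Probe set 1427000_at read 344, 348 and 358 in the arrays null_59, null_60 and null_426 and 640 and 442 in CONTROL_406 and CONTROL_421, a log2 difference of -0.55 ± 0.19 (SE, adjusted p = 0.603). Probe set 1427001_s_at, the brightest, read 706 ± 50.1 (SD, n = 3) in null and 968 ± 32.6 (SD, n = 2) in control colons, a difference of -0.35 ± 0.17 (SE, adjusted p = 0.719). The intensities of 1421983_s_at were 378, 322 and 367 in null against 426.2 and 249 in control colons, a difference of 0.14 ± 0.22 (SE, adjusted p = 0.902) that turned to -0.20 without CONTROL_421. Those of 1450447_at were 332, 325 and 399 against 342 and 283, a difference of 0.19 ± 0.18 (SE, adjusted p = 0.836). The labels do not say which part of the gene lies between the loxP sites, and a probe set outside the deleted part checks nothing. For the paralog Hnf4g, which is outside the rule for named genes, the difference was 0.19 ± 0.21 (SE, adjusted p = 0.858).

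Saa1, which encodes an acute-phase serum amyloid A protein, fell most in HNF4 null colons among the named genes, with deposited intensities of 87.9 ± 53.0 (SD, n = 3) in null and 894 ± 85.5 (SD, n = 2) in control colons. Its fold difference was 9.34 (95% interval 5.46 to 15.98, adjusted p = 0.0103). Atp12a, the catalytic subunit of the non-gastric proton-potassium pump of the colon, was 7.61-fold lower (4.18 to 13.8, adjusted p = 0.0271), at 170 ± 85.5 against 1309 ± 195. Zg16, a lectin-like protein secreted by goblet cells, was 6.31-fold lower (4.10 to 9.72, adjusted p = 0.0103), at 209 ± 74.5 against 1405 ± 203. The water channel gene Aqp8 was 5.67-fold lower (4.19 to 7.67, adjusted p = 0.00654), at 72.2 ± 13.4 against 477 ± 9.87. Saa2, a near-identical paralog of Saa1, was 6.01-fold lower (adjusted p = 0.00693), and how far each array probe set separates the 2 genes is uncertain.

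Among the other large decreases, Cyp2d26, a cytochrome P450, was 5.64-fold lower and Sult1b1, a cytosolic sulfotransferase, was 5.13-fold lower. Steap4, a metalloreductase, and Muc3, a membrane mucin of enterocytes, were 4.22-fold and 4.19-fold lower, and a second, dimmer probe set of Steap4 was 1.71-fold lower (adjusted p = 0.617). Selenop, which encodes the secreted selenium carrier selenoprotein P, was 3.98-fold lower, at 544 ± 163 (SD, n = 3) in null and 2224 ± 271 (SD, n = 2) in control colons. Cdhr5, a protocadherin that links microvilli, and Slc39a4, a zinc importer, were 3.72-fold and 3.70-fold lower. The adjusted p of these 7 genes lay between 0.00693 and 0.0432, and in each the 3 null arrays lay below both control arrays, as the rule for named genes required. Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages, was 3.55-fold lower (adjusted p = 0.0271) by its brighter probe set and 1.85-fold lower by the other (adjusted p = 0.311), and the sulfotransferase gene Sult1d1 and the meprin gene Mep1b were 3.22-fold (adjusted p = 0.0432) and 2.89-fold lower (adjusted p = 0.0103). Clec2h, a C-type lectin gene, passed by the 2 dimmer of its 3 probe sets, 7.18-fold (adjusted p = 0.0106) and 4.37-fold lower (adjusted p = 0.0439). By its brightest probe set it was 1.83-fold lower (adjusted p = 0.298). Outside the rule for named genes and chosen after their values were seen, Aqp4, Ttyh2 and Gm8479 were each past the threshold by 1 of 2 probe sets, 3.50-fold, 3.00-fold and 2.38-fold lower, while the brighter probe set of each differed by -0.23, -0.13 and -0.0034 on the log2 scale.

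**Figure D1:**
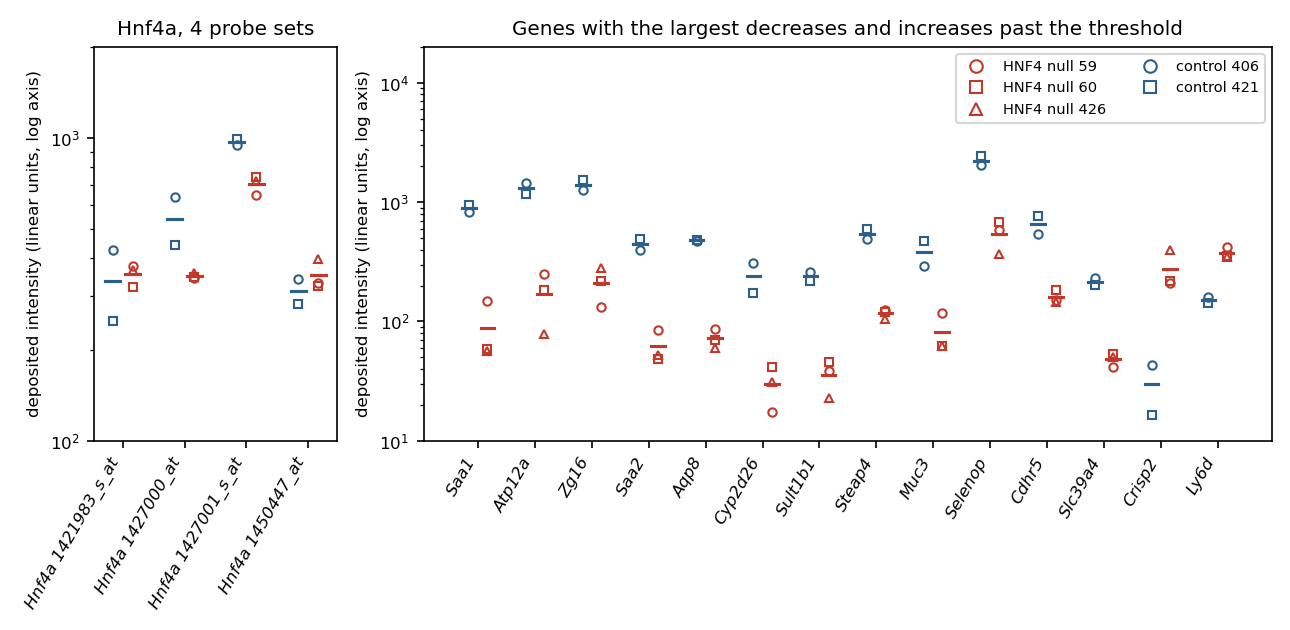
Deposited intensity (linear units on a log axis) of the 4 Hnf4a probe sets and of the 14 genes with the largest decreases and increases past the threshold by each gene's brightest probe set, 1 point per array, with lines at the group means of 3 HNF4 null and 2 control arrays. Every null array lies below both control arrays for the 12 genes from Saa1 to Slc39a4 and above both for Crisp2 and Ly6d, as the rule for named genes required.

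Few genes were higher in HNF4 null colons. Crisp2, a cysteine-rich secretory protein best known from the male reproductive tract, read 275 ± 106 (SD, n = 3) in null and 29.6 ± 18.6 (SD, n = 2) in control colons, a 6.19-fold rise (95% interval 3.82 to 10.03, adjusted p = 0.0136). Ly6d, which encodes a membrane-anchored Ly6 protein, read 373 ± 38.4 against 151 ± 12.6, a 2.31-fold rise (1.78 to 3.01, adjusted p = 0.0430). By probe sets other than the gene's brightest, and chosen after their values were seen, Mal, a proteolipid of membrane transport, was 4.43-fold higher and the water and glycerol channel gene Aqp3 was 3.30-fold higher (both adjusted p = 0.0103). The brightest probe sets of Mal and Aqp3 differed by 0.28 and 0.37 on the log2 scale, the third and dimmest one of Aqp3 differed by 0.84, and none of these was past the threshold.

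In all, 28 of 22626 probe sets passed limma's threshold, 24 lower and 4 higher in HNF4 null colons, and they named 23 genes, 19 lower and 4 higher. All 28 changed at least 2-fold. At an unadjusted p under 0.05, 1618 probe sets differed (638 higher and 980 lower) against 1131 expected with no effect, and the other 9 splits of the 5 arrays into 3 and 2 gave from 337 to 2375, with 2 of them above the real one (1918 and 2375). The excess at this level is therefore not specific to the genotype. The count was 8 (0 higher and 8 lower) without HNF4 null_60, 104 (57 higher and 47 lower) without CONTROL_406 and 18 (5 higher and 13 lower) without CONTROL_421, and it was 14 with a pseudocount of 1, 17 after removal of dim probe sets and 45 with array weights.

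Aqp8, Sult1b1, Slc39a4 and, by its brighter probe set, Steap4 stayed past the threshold with any 1 array left out (adjusted p up to 0.0482). The other 10 of the 14 genes with the largest changes by their brightest probe sets were not past it without HNF4 null_60, with adjusted p from 0.0600 for Cyp2d26 to 0.209 for Muc3. By their brightest probe sets, Saa1, Atp12a, Zg16, Muc3, Selenop, Cdhr5, Crisp2 and Ly6d were not past it without CONTROL_421 either, with adjusted p from 0.0545 to 0.251, while the dimmest of the 3 probe sets of Zg16 stayed past it there (0.0328). Atp12a had an adjusted p of 0.0657 without CONTROL_406, Muc3 one of 0.185 without HNF4 null_426, and Ly6d passed in none of the 5 fits (0.0680 to 0.244). Lyve1 had an adjusted p of 0.146 without HNF4 null_60 and 0.193 without CONTROL_421, Mep1b one of 0.0674 without HNF4 null_60 and Mal one of 0.0899 without it. Aqp3 had one of 0.0774 without HNF4 null_60 and 0.0649 without CONTROL_421, and Clec2h, by the probe set with the larger fall, one of 0.0579 without CONTROL_421, while its probe set with the smaller fall passed only without HNF4 null_59 (0.0328 against 0.0579 to 0.147). Sult1d1 passed only without CONTROL_421 (0.0328 against 0.0726 to 0.185) by its brightest probe set, Aqp4 only without HNF4 null_60 (0.0482 against 0.0531 to 0.0837), Ttyh2 only without either control array (0.0328 and 0.0381 against 0.0507 to 0.0760) and Gm8479 in none of the 5 fits (0.0686 to 0.117).

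Genes of enterocytes and the brush border, the microvillar surface of absorptive cells, stood lower as a group. Of 26 measured members, 2 fell at the threshold over all probe sets (Cdhr5 and Mep1b) and 24 did not pass, while 12 were lower adjusted over the list alone. Examples among these were the amino acid transporter gene Slc7a9 (-0.89 on the log2 scale), the peptide transporter gene Slc15a1 (-1.62), villin, Vil1 (-0.74), the keratin gene Krt20 (-0.87) and the microvillus gene Eps8l3 (-0.86). The mean log2 difference was -0.47 and the median -0.28 (camera adjusted p = 1.25e-08, and adjusted p = 0.164 with an estimated correlation). The correlation estimated for this list was 0.0011, below the preset 0.01, so correlation between its members does not account for the higher p. In fry, which tests whether the members move 1 way, the adjusted p was 0.0334 for this list. By fry it was 0.142 for colonic ion and water transport and 0.236 for xenobiotic metabolism, so neither of these lists passed. Slc15a1, Vil1 and Krt20 were chosen after their values were seen.

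Colonic ion and water transport genes were lower by camera with a mean of -0.32 and a median of -0.05 over 25 members (adjusted p = 0.00418, and adjusted p = 0.363 with an estimated correlation). The correlation estimated for this list was -0.0046, also below the preset one. By each gene's brightest probe set, Aqp8 and Atp12a passed and 23 members did not. Aqp4, 1 of these, passed by its dimmer probe set. Adjusted over the list alone, 3 were lower, the third being the anion channel gene Best2 (-0.91). The fatty acid transporter gene Slc5a8 differed by -0.64. Without HNF4 null_60 the list had an adjusted p of 0.0845, against 0.000503 to 0.0243 in the other alternatives with the preset correlation. Xenobiotic metabolism genes had a mean of -0.27 and a median of -0.11 over 35 members (adjusted p = 0.0136, and adjusted p = 0.528 with an estimated correlation). Here the estimated correlation was 0.022, above the preset one. Sult1b1, Cyp2d26 and Sult1d1 fell and 32 members did not pass, while 4 were lower and 1 higher adjusted over the list alone, the last being the epoxide hydrolase gene Ephx2 (0.70). The filter on dim probe sets used the mean over all arrays. It took out Sult1b1, Cyp2d26 and Sult1d1, whose mean control intensities of 239, 241 and 167 lay above the array medians. After removal of dim probe sets, which left 13 members, the mean of this list was 0.05 (adjusted p = 0.804, against 0.00612 to 0.0489 in the other alternatives with the preset correlation).

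Genes of other epithelial programmes did not pass as groups. In the goblet cell list, 1 of 24 members fell (Zg16) and 3 were lower adjusted over the list alone, with the mucin gene Muc13 (-0.94) and the guanylin gene Guca2a (-0.72), while Sytl2, a vesicle transport gene, differed by 0.52. The median of this list was 0.05, its mean -0.09 and its camera direction down (adjusted p = 0.711). The trefoil factor gene Tff3 (-0.06), chosen after its value was seen, had 4918 ± 333 (SD, n = 3) in null and 5192 ± 288 (SD, n = 2) in control colons. Of 22 endoderm transcription factors 0 passed limma's threshold and 3 were lower at an unadjusted p under 0.05, with 0 adjusted over the list alone. These were Cdx1 (-0.78), Foxa2 (-0.55) and Klf4 (-0.65), and the list's mean was -0.11 (adjusted p = 0.511). Of 34 genes of epithelial junctions and keratins 0 passed over all probe sets, 7 at an unadjusted p under 0.05, and 1 was higher and 1 lower adjusted over the list alone. The claudin gene Cldn1 differed by 0.71, the adhesion gene Epcam by -0.66, the connexin gene Gjb1 by -0.69 and the cadherin gene Cdh17 by -0.86, and the list's mean was -0.10 and its median -0.07 (adjusted p = 0.149). Of 13 genes higher in small intestine than in colon, 2 were lower adjusted over the list alone, Clec2h by its brightest probe set (-0.87) and the bile acid transporter gene Slc10a2 (-0.68), with a mean of -0.19 (adjusted p = 0.0629). By limma and each gene's brightest probe set, 0 of the 13 passed over all probe sets and 3 were lower at an unadjusted p under 0.05. The 2 dimmer probe sets of Clec2h did pass. In the enteroendocrine list, 1 of 27 members was lower adjusted over the list alone, the neurotensin gene Nts (-1.01), with the tachykinin gene Tac1 at -0.59 and a mean of -0.04 (adjusted p = 0.729), and 0 passed limma's threshold over all probe sets against 3 lower at an unadjusted p under 0.05. The 31 genes of lipid transport and apolipoproteins had a mean of -0.06 (adjusted p = 0.511), with 0 past limma's threshold and, at an unadjusted p under 0.05, 1 higher (Apom, 0.44) and 1 lower (the lipid droplet gene Cideb, -0.39).

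**Figure D2:**
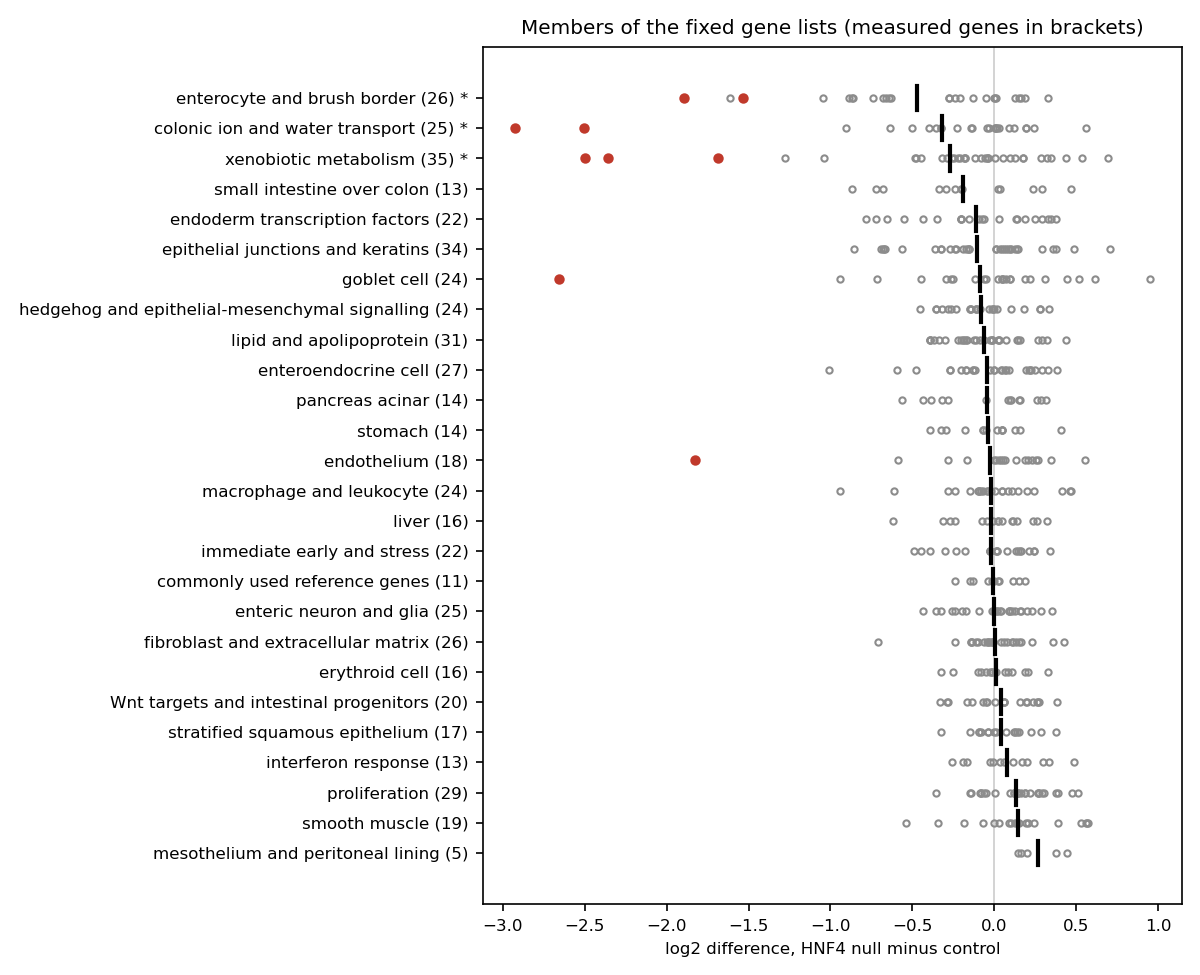
Log2 difference (HNF4 null minus control) of the measured members of 26 gene lists, 1 point per gene, with the mean of each list as a black bar, genes past the threshold over all probe sets as filled red points and lists past it by camera with the preset correlation marked by a star. The 3 starred lists are those of enterocytes, colonic transport and xenobiotic metabolism, with means of -0.47, -0.32 and -0.27. With an estimated correlation their adjusted p by camera was 0.164, 0.363 and 0.528.

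Proliferation genes had a mean of 0.13 over 29 members (adjusted p = 0.0567), with the forkhead gene Foxm1 at 0.51, Mki67 at 0.48, the topoisomerase gene Top2a at 0.39 and the centromere gene Cenpa at -0.36, and 8 members were below 0. Smooth muscle genes had a mean of 0.14 over 19 members (adjusted p = 0.0824), with the contractile genes Myh11 at 0.57, Tagln at 0.56 and Tpm1 at 0.53 and the calsequestrin gene Casq2 at -0.54, and 5 members were below 0. The 5 measured genes of the mesothelium, the lining of the peritoneum, had a mean of 0.27 (adjusted p = 0.0628), with Wt1 at 0.44 and Msln at 0.38. Without CONTROL_421, the array with the high Gapdh ratio, the means of these lists were 0.10, 0.06 and 0.08, and without CONTROL_406 they were 0.16, 0.23 and 0.46 (adjusted p = 0.0385, 0.0141 and 0.00726). These p-values use the preset correlation, and with an estimated correlation over all 5 arrays the adjusted p was 0.805 for each of the 3 lists. Wnt targets and intestinal progenitors had a mean of 0.04 (adjusted p = 0.729), with the stem cell marker Lgr5 at -0.28 and Prom1 at 0.38. Genes of hedgehog and epithelial-mesenchymal signalling had a mean of -0.08 (adjusted p = 0.350), with Foxf2 at -0.45. The interferon response had a mean of 0.08 (adjusted p = 0.564) with Usp18 at 0.48, and the macrophage and leukocyte list one of -0.02 (adjusted p = 0.897) with the cathepsin gene Ctss at -0.94 and S100a8 at 0.46. The stomach list had a mean of -0.04 (adjusted p = 0.711) and the stratified squamous list one of 0.04 (adjusted p = 0.853), with Krt4 at 0.38. In these lists 0 members passed limma's threshold over all probe sets and 0 adjusted over the list alone. At an unadjusted p under 0.05, 4 smooth muscle genes were higher and 1 lower, 1 macrophage and leukocyte gene was higher and 2 lower, and 1 gene each of the mesothelium (Wt1, higher), hedgehog (Foxf2, lower) and interferon (Usp18, higher) lists differed.

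In several lists the median, the mean and the direction of the test, which is relative to the other genes, differed in sign. In the endothelium list the median was 0.06, the mean -0.03 and the camera direction up (adjusted p = 0.897), with 1 of 18 members lower over all probe sets and adjusted over the list alone (Lyve1). The medians were 0.09 for pancreas, 0.03 for enteric neurons and glia and 0.01 for immediate early and stress genes, against means of -0.04, -0.0031 and -0.02, all with a camera direction down (adjusted p = 0.729, 0.897 and 0.897). For fibroblasts and matrix, the median was -0.0097, the mean 0.0024 and the direction down (adjusted p = 0.897), with the periostin gene Postn at -0.71. For erythroid cells the median was -0.0047, the mean 0.0076 and the direction down (adjusted p = 0.917). For liver the median was 0.02, the mean -0.02 and the direction up (adjusted p = 0.984), and for the reference genes, such as Actb at -0.24 (0.17 with the mean of its probe sets) and Ywhaz at -0.15, the median was 0.0014, the mean -0.0057 and the direction down (adjusted p = 0.897). Apart from Lyve1, 0 members of these lists passed limma's threshold over all probe sets and 0 adjusted over the list alone, with 3 pancreas genes and Postn lower at an unadjusted p under 0.05.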

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

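No alternative setting reported here was added after the results had been seen. Each of the 28 probe sets past the threshold kept its direction in every setting that tested it, and 14 of them were not tested after removal of dim probe sets. Null and control arrays did not overlap in any of the 28, so leaving out 1 array could hardly turn a direction. All 28 stayed past the threshold in the table as deposited (32 called), with median centring (31) and with the variance trend (33), and 26 did with the robust trend (37). A pseudocount of 1 gave 14 probe sets, 4 higher and 10 lower, 9 of them from the 28, and a pseudocount of 64 gave 22, with 2 higher. Removal of dim probe sets, which left 11313 to be tested, gave 17 with 1 higher, and array weights gave 45, 7 higher and 38 lower. The share that was lower was 85.7% in the main setting, 71.4% with a pseudocount of 1 and 45.2% without CONTROL_406. With 1 array left out the total ran from 8 without HNF4 null_60 (0 higher, 8 lower) to 104 without CONTROL_406 (57 higher, 47 lower), and it was 18 without CONTROL_421. Of the 104, 69 had the same direction without CONTROL_421, and 10 were called in both fits. The cause of these differences was not tested, apart from the smaller number of probe sets tested after the dim ones were removed.

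Against 3 gene lists past the threshold, 6 passed with the variance trend, 5 with array weights, 6 with the mean of a gene's probe sets and 0 with an estimated correlation (2 at an unadjusted p under 0.05). The robust option was not passed to camera, so it gave no separate result for the lists. The enterocyte list passed in every setting (adjusted p from 4.27e-10 to 6.96e-05) except the estimated correlation (0.164). The mean of the xenobiotic list was 0.048 when dim probe sets were removed, which took out the members past the threshold, Sult1b1, Cyp2d26 and Sult1d1. The lists that passed only in alternatives were proliferation, smooth muscle and mesothelium, with a direction up, and epithelial junctions and small intestine over colon, with a direction down. Hnf4a, taken as the mean of all its probe sets, differed by -0.14, against 0.14 and 0.19 for probe sets 1421983_s_at and 1450447_at alone. Probe set 1421983_s_at ran from -0.20 without CONTROL_421 to 0.47 without CONTROL_406. The mean of a gene's probe sets differed by -0.075 for Bmp7, 0.17 for Actb and -0.020 for B2m, against 0.28, -0.24 and 0.19 by their brightest probe sets. Between the fits without CONTROL_421 and without CONTROL_406, Mfap2 ran from -0.090 to 0.94, Mfap4 from -0.16 to 0.87, Upk3b from -0.042 to 0.44, Gpm6a from -0.040 to 0.38, Rplp0 from -0.051 to 0.35 and B2m from -0.052 to 0.42. Hbb-y ran from -0.050 without HNF4 null_426 to 0.63 without HNF4 null_60. The cause was not tested. No paired analysis was possible because the null and control embryos share no replicate number. Signal over background limits the dim genes, since between 3.18% and 4.86% of the values of an array lay below 16, and no detection calls were used here.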

Other observations

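Below the threshold, at adjusted p values between 0.05 and 0.10, 13 further probe sets stood next to those past it, and their genes were chosen after their values were seen. Lower in HNF4 null colons were the sulfate transporter gene Slc26a2 (4.34-fold, adjusted p = 0.0567), the iron exporter gene Slc40a1 (2.14-fold, adjusted p = 0.0945) and the claudin gene Cldn2 by the dimmer of its 2 probe sets (2.35-fold, adjusted p = 0.0557, against -0.16 on the log2 scale by the brighter one). Also lower were the cubilin gene Cubn by its dimmer probe set (2.32-fold, adjusted p = 0.0567, against -0.66 by the brighter one), the epithelial gene Phgr1 (2.54-fold, adjusted p = 0.0557), the rhodanese gene Tst (2.74-fold, adjusted p = 0.0660) and Calml4, a calmodulin-like gene of the brush border (2.50-fold, adjusted p = 0.0829). The chemokine gene Ccl6 was 2.90-fold lower by its dimmer probe set (adjusted p = 0.0573), while the brighter one differed by -0.16 on the log2 scale. Higher, by probe sets other than the brightest, were Meg3, an imprinted noncoding RNA (2.07-fold, adjusted p = 0.0829, against 0.75 by the brightest), and Opn1sw, a cone opsin gene (3.14-fold, adjusted p = 0.0829, against 0.31).

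Posterior Hox genes, which mark position along the hindgut, had a median log2 difference of -0.05 over 13 measured members, none of which another list holds. Hoxc9 (-0.69), Hoxb13 (-0.75) and Hoxa13 (-0.55) were the members with an unadjusted p under 0.05, and 0 passed the threshold. The Xist probe set 1436936_s_at read 785, 626 and 99.7 in HNF4 null_59, null_60 and null_426, and 450 and 342 in CONTROL_406 and CONTROL_421. Of the dimmer Xist probe sets, 1427262_at read 51.6, 92.9 and 41.5, and 66.6 and 74.2. The other, 1427263_at, read 94.5, 101 and 130, and 95.3 and 89.4. The Eif2s3y probe set, of a Y-linked gene, read 12.4, 25.5 and 47.0, and 21.4 and 19.0. Each probe set of the Y-linked genes Kdm5d and Uty was also highest in HNF4 null_426. Sex was not a covariate, and whether the groups differed in it was not tested.

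Of the tests that follow, those on the epithelial share, the stratified squamous list and the splits of the arrays were chosen after the values they measure had been seen. The test on the posterior Hox genes was set before, and the further look at its single members was added after its values were seen and reopened an explanation that the median alone would have excluded. The same holds for the look at the brighter members of the resident macrophage and lymphatic lists, which reopened the lymphatic one.

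For the fall of 24 probe sets in HNF4 null colons, a smaller share of epithelial cells would lower general epithelial genes about as much, but the junction and keratin list had a median of -0.0734 (95% interval -0.23 to 0.07) against -2.07 for the probe sets that fell, which argues against it as the whole cause of falls of that size. The -2.07 is from probe sets picked for their fall in these same data, so a list not so picked lies above it easily. A part for the epithelial share in the shift of the enterocyte list stays open, since the median of the junction and keratin list stood at percentile 2.07 of 10000 random lists of like level. With the mean of a gene's probe sets its median was -0.14, and it was lower by camera with the preset correlation (adjusted p = 0.0116). The abundant members went both ways, with Krt8 at 4267 in null and 4808 in control colons, Epcam at 1483 and 2454 and Krt18 at 1541 and 1331. The Gapdh ratio of CONTROL_421 was high while its other 2 control ratios were not the highest. The RNA quality of this array is not needed for the enterocyte shift, since without it the enterocyte list had a mean of -0.49. That mean rests on 1 control embryo, CONTROL_406. With an estimated correlation and all 5 arrays the list did not pass (camera adjusted p = 0.164). For another segment of the hindgut, the median of the posterior Hox genes was -0.0533 (95% interval -0.32 to 0.05, percentile 18.3 of 10000 random lists of like level) and met the bound of 0.5 set to exclude it, but Hoxb13, Hoxa13 and Hoxc9 lay beyond -0.5 and a shift along the hindgut may move only some of these genes, so that bound was wrong and the segment stays open. The genotype, acting on these genes directly or through delayed maturation of the epithelium, stays open as a hypothesis, and neither route was tested.

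The genes that rose, Crisp2, Mal, Aqp3 and Ly6d, might have come from a neighbouring epithelium carried along in dissection. The stratified squamous list had a median of 0.00795 (95% interval -0.08 to 0.14) and the urothelium list, with 11 measured members of which 3 are in other lists, one of 0.153 (95% interval -0.03 to 0.27), and both intervals end below 0.97, which is 0.5 of the median rise of these probe sets. That bound comes from probe sets picked for their rise in these same data, so a list not so picked meets it easily. The most abundant members were Krt15, at 488 in null and 475 in control colons, and Krt7, at 649 and 508. The squamous list, with a median near 0 over 17 members, argues against that tissue as the whole source of the rise. For urothelium the bound on log2 differences cannot decide, since carried tissue adds intensity and Krt7 was already bright in control colons. In mean intensity Krt7 rose about as much as Mal (132 and 15.0) and Aqp3 (148 and 30.9). Of the urothelium list only Krt7, Upk1a and Upk2 (420 and 393) lay above the median control intensity of 127.9. Urothelium stays open as a source. That list stood at percentile 96.2 of the random lists, with Upk1a at 238 and 185 and Psca at 95.4 and 72.3. Upk3a was lower, at 39.9 and 55.2. A change within the colonic epithelium, or another tissue for which no list was tested, stays open.

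The lower levels of Lyve1 and Selenop, genes that macrophages also express, could reflect fewer resident macrophages or fewer lymphatic vessels, for which a bound of -0.95, 0.5 of the mean of the 2 genes, was set. The 2 genes were picked for their fall in these same data, so a list not so picked meets this bound easily. Without these genes, the resident macrophage list had a median of -0.0855 (95% interval -0.15 to -0.03) over 20 members, 6 of them in other lists, and the 14 members above the median control intensity of 127.9 had one of -0.10 (95% interval -0.16 to -0.04), with Csf1r at 486 in null and 525 in control colons and Adgre1 at 263 and 271. These values argue against a loss of resident macrophages as the whole cause. A smaller loss or one of some macrophages stays open, since the list of 20 stood at percentile 4.48 of 10000 random lists of like level. Also, Ctss (-0.94), Cd14 (-0.61) and the dimmer probe set of Ccl6 were lower, and no detection calls were used. None of these was past the threshold (limma adjusted p = 0.437 for Ctss and 0.642 for Cd14). Fewer lymphatic vessels stay open although the median of that list (-0.0622, 95% interval -0.15 to 0.13) met the bound and Prox1 (0.34), Pdpn (-0.15) and Nrp2 (-0.01) go against them, because only Pdpn and Nrp2 of its 10 members lay above that intensity (with Prox1, 3 by the mean of all arrays) and a bound on probe sets this dim was wrong. A change within the cells that express Lyve1 and Selenop was not tested.

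The 5 arrays can be split into groups of 3 and 2 in 10 ways, too few for a share under 0.05. The real split gave 28 probe sets past the threshold and the highest of the other splits gave 1.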
